A study of Mus musculus with 4 samples.

How the data were processed

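Lung RNA of 4 groups of C57BL/6 mice was sequenced, with 1 library per group: wild type after house dust mite (HDM), Il22 knockout after HDM, wild type after PBS and wild type after recombinant IL-22. The groups were taken from the sample titles. Per the labels' protocols, RNA was isolated with a column kit from frozen lungs and made into standard Illumina libraries. The deposited values are FPKM per gene, in 1 table for the HDM pair and another for the PBS and IL-22 pair, and the submitters' processing notes name CASAVA 1.8.2, TopHat2, Cufflinks 2.2.1 and the mouse build mm10. The settings of these tools and any scaling between libraries are not given in the sources used here.

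Each table held 23746 rows with a symbol and RefSeq accessions. The tables list the same rows but 4564 of them stand in another order, so they were joined on symbol and accession. For 25 symbols that had been turned into dates, the symbol was restored from the accession. Accessions of 98.0% of rows matched a RefSeq gene table of GRCm38, the assembly called mm10. Rows of the same symbol were added together, which left 23284 genes. Coordinates are from GENCODE M21 on the same assembly, and older symbols in the tables are given with the current name where these differ.

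FPKM values are not counts, and the depth was recovered from their steps. In low rows a value is a whole multiple of what 1 read is worth, so the most frequent ratio between libraries gives the relative depth: the knockout HDM library was 1.09 times, the PBS library 0.801 times and the IL-22 library 1.16 times as deep as the wild-type HDM library. With transcript lengths from GENCODE, the value of 1 read times the length less 200 bases had a common value in most low rows. Of 531 such rows, 382 lay within 15% of it. This gave 24.95, 27.3, 19.98 and 28.9 M reads (M for 1000000) for the wild-type HDM, knockout HDM, PBS and IL-22 libraries. Of 8543 low values of genes with a single accession, 62.1% came out within 0.1 of a whole read, where chance gives 20%. A transcript length that differs from the one used, or reads shared with other genes, would put a value off a whole read, and this was not tested. Reads are printed only for genes of few reads, rounded to whole numbers. Ratios of such reads have exact binomial 95% intervals, which cover counting error only. A gene at 0 reads was set at a floor of 3 counts. The count of the other library was then taken as exact, so such a fold is not a lower bound. Reads drawn at these depths from 1 common level per gene, in 100 draws over rows of more than 400 bases, put on average 0.17 genes above and 0.17 below the size rule in the HDM pair (44 and 288 observed) and 0.22 and 0.20 in the PBS and IL-22 pair (59 and 4 observed). Counting error is therefore small beside the differences, but spread between animals was not measured.

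Differences are those of log2(FPKM + 1) between the libraries of a table, over genes with a mean FPKM of at least 1. A gene was called higher or lower at a difference of at least 1 in size, and no p-value was computed. There were 47 gene lists fixed before the data were examined, 26 of them cell type markers. Each list with at least 3 measured genes was described by its median and the percentile of that median among 10000 random lists matched in 20 expression bins. Genes named in the text were chosen by a rule written at the same time: the 15 largest differences each way, leaving out predicted and unnamed genes, small RNAs and immunoglobulin or T cell receptor segments, up to 4 members of each list with the largest differences, and Il22, Iltifb, Reg3g, Reg3b, Il4, Il5, Il13, Ccl11, Ccl17, Ccl22, Ccl24, Muc5ac and Il22ra1 whatever their values. Genes left out of naming by class numbered 11 higher and 21 lower predicted or unnamed genes and 22 higher and 23 lower small RNAs in the HDM pair, and 3 and 1 and 17 and 19 in the other pair. Further list members are named as examples with their values, chosen after these were seen. Xist was expressed and the Y-linked genes were near 0 in all 4 libraries. The steps were tested on simulated data, with differences planted only in genes with a mean FPKM of at least 2. Of 100 genes planted at 3-fold and 100 at 6-fold, 93 and 100 were called among 12966 genes of the HDM pair. In the other pair 97 and 100 were called among 12907 genes. Recovery of genes nearer the filter was not tested. The simulated depths were recovered, from reads built with the same length less 200 bases that the fit uses. Of 100 random lists of unchanged genes, 2 and 8 fell outside the middle 95% of matched lists.

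The alternatives were a pseudocount of 0.1, scaling by the median ratio or to a common total, no filter or a mean FPKM of at least 5, a size rule of 1.5, and 10 expression bins. Leaving out small RNAs, or the fat and muscle lists, was added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.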

Results

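RNA was sequenced from whole lungs of C57BL/6 mice in 4 libraries, 1 per group. Wild-type mice and mice lacking Il22, the gene of the cytokine interleukin-22, had been sensitized to and challenged with house dust mite (HDM), an allergen used to model asthma, and their lungs were taken 48 h after the last exposure. A separate pair of wild-type lungs was taken 24 h after phosphate-buffered saline (PBS) or recombinant IL-22 had been placed in the airways. The values were FPKM, which scale fragments by transcript length and sequencing depth. By the whole-read steps of the low values, the knockout HDM library was 1.09 times, the PBS library 0.801 times and the IL-22 library 1.16 times as deep as the wild-type HDM library, which had an estimated 24.95 M reads (M for 1000000). Scgb1a1, the secretoglobin of club cells, took 17.6 to 20.5% of the total FPKM of each library. With 1 library per group, no difference given here has a replicate check, and the labels do not say whether a library is 1 animal or a pool. Differences are of log2(FPKM + 1), which understates those of low genes, and a gene is called higher or lower where this difference is at least 1 in size and the mean FPKM at least 1. For each gene list the percentile of its median among 10000 random lists matched on expression is given as a description of these libraries.

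The knockout was compared with wild type to ask what the loss of IL-22 does to the lung during allergic inflammation. Il22 (chromosome 10, 118204942 to 118210047 of mm10, protein coding) had an FPKM of 0.362 in the wild-type HDM library, which is 8 reads, and was listed at 0 in the knockout. Its near-identical neighbour Iltifb (chromosome 10, 118289629 to 118295038) had 5 reads in wild type and was also listed at 0 in the knockout. The 13 reads of the pair can be split between the copies. Together they were 4.74-fold lower in the knockout when its 0 reads are set at the floor of 3 counts. The 13 reads are taken as exact here, so this fold is not a lower bound. Both genes were also listed at 0 in the PBS and IL-22 libraries of wild-type mice, so a value of 0 by itself does not tell a knockout from an unchallenged wild type. Of 17 measured genes that flank Il22 on chromosome 10, none was higher and none lower, and their median difference was 0.07.

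Genes of the type 2 response, which IL-4 and IL-13 drive in the allergic lung, were lower in the HDM-treated knockout library than in the HDM-treated wild-type library. Of 13285 measured genes, 322 were lower and 73 higher. Among 22 measured type 2 effector genes 19 were lower and none higher, with a median difference of -2.20, a fold of 4.60, below all 10000 random lists. Goblet cell and mucus genes, chemokines, the type I interferon response and cell cycle genes were lower as groups, while haemoglobin and other erythroid genes were higher. Most of the measured genes, 90.4%, lay within 1.5-fold between the libraries, and the median of all genes was 0.03.

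The largest difference outside the small RNAs was that of Ear11 (annotated as Rnase2a, chromosome 14, 51255262 to 51256112), an eosinophil-associated ribonuclease family member, at 195 FPKM in wild type and 5.71 in the knockout. Ccl24 (chromosome 5, 135569937 to 135573049) and Ccl11, the eotaxins that draw eosinophils, had differences of -3.55 and -2.18, with Ccl24 at 16.2 against 0.471 FPKM. Ccl8 (chromosome 11, 82115185 to 82116799) was at 165 against 12.3, and Ccl17, a ligand of CCR4 on type 2 helper T cells, at 296 against 47.6. Retnla (chromosome 16, 48842551 to 48844461), a secreted product of alternatively activated macrophages and airway epithelium, was at 19372 FPKM in wild type and 3511 in the knockout. The chitinase-like genes Chi3l3 (Chil3, chromosome 3, 106147554 to 106167564) and Chi3l4 (Chil4, chromosome 3, 106201490 to 106219507) had differences of -2.73 and -3.06. Fbp1, a gluconeogenic enzyme also found in macrophages, was at 22.2 against 0.505, and Arg1, the arginase of alternatively activated macrophages, had a difference of -2.62. Postn, a matrix protein gene, was the only measured member above 0, at 0.34. Chi3l3, Chi3l4 and Ear11 have close paralogs with which reads can be shared.

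Of 12 measured goblet cell and mucus genes 7 were lower and none higher (median -1.37, below all random lists). Muc5ac (chromosome 7, 141788972 to 141819231), the gel-forming mucin of goblet cells, was at 9.43 FPKM in wild type and 0.963 in the knockout. Clca3 (Clca1, chromosome 3, 145003817 to 145032776), a goblet cell secreted protein, was at 1343 against 326. Slc26a4 (pendrin, chromosome 12, 31519827 to 31559969), an anion exchanger, was at 52.9 against 3.36, and Agr2, a disulfide isomerase needed for mucin folding, at 44.5 against 8.87.

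The cytokines themselves were near the limit of detection. Il13 had 19 reads in the wild-type HDM library, with a 95% counting interval of 11.4 to 29.7, and was listed at 0 in the knockout. That is 6.93-fold lower with the knockout at the floor of 3 counts and the 19 reads taken as exact. Il5 had 12 and 9 reads, a ratio of 0.686 with an exact 95% interval of 0.255 to 1.77, so no difference was detectable at this depth, and Il4 had 2 and 1 reads, a ratio of 0.457 (0.00775 to 8.78). The intervals cover counting error only, and the floors leave out that of the wild-type count. Both compare these libraries, not the genotypes. Il33, an alarmin of epithelium, was at 167 FPKM against 58.2, and was the only called member of the cytokine and alarmin list, whose 8 measured genes had a median of -0.44.

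Of 27 measured chemokines 18 were lower and none higher, with a median of -1.38. Besides the type 2 chemokines these included the monocyte chemokine Ccl12 (17.2 against 1.10 FPKM) and the neutrophil chemokines Cxcl1 (11.5 against 1.08) and Cxcl5 (6.03 against 0.252). Ccl22 was at 20.4 against 10.1, just short of the size rule. Among 20 type I interferon response genes 15 were lower and none higher (median -1.42, below all random lists), with Irf7 (chromosome 7, 141262706 to 141266481), a transcription factor of that response, at 66.8 against 8.23, Isg15 at 66.4 against 9.44 and Oasl2 at 57.9 against 11.5. Of 19 interferon gamma and antigen presentation genes 7 were lower, with Cxcl10 at 11.9 against 1.39 and a median of -0.89. Ifng itself had 4 and 2 reads.

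Cell cycle genes were lower in 15 of 18 measured members (median -1.29). Top2a, the topoisomerase of dividing cells, was at 7.57 against 1.65 FPKM, Birc5 at 13.1 against 3.35 and Ube2c at 18.8 against 6.07.

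Genes known to respond to IL-22 or STAT3 in epithelium lay mostly below 0, with exceptions. Of 20 measured, 16 lay below 0, and 6 were lower and 2 higher by the size rule (median -0.59, below all random lists). Reg3g (chromosome 6, 78466269 to 78468872), a C-type lectin against bacteria and a classical IL-22 target, was at 214 FPKM in wild type and 43.4 in the knockout, a difference of -2.28. Saa3, an acute phase protein gene, was at 130 against 8.15, and Lcn2, the siderophore-binding lipocalin, at 1663 against 284. S100a8 and S100a9, calgranulins abundant in neutrophils, were higher in the knockout by 1.11 and 1.19. Reg3b was listed at 0 in all 4 libraries. Il22ra1, the IL-22 receptor chain, was at 1.11 against 0.818 FPKM.

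Markers of cell types also differed between the libraries. Monocyte and interstitial macrophage markers were lower in 9 of 17 genes (median -1.09), with the macrophage elastase Mmp12 at 37.5 against 2.25 FPKM and the complement genes C1qa and C1qb at 132 against 42.5 and 153 against 43.2. Alveolar macrophage markers had a median of -0.79, dendritic cell markers -0.68, T cell markers -0.58 and eosinophil markers -0.57. Among the eosinophil markers Prg2, the major basic protein, had 45 reads against 3, a ratio of 0.0610 (0.0121 to 0.190). Only 6 of the 12 eosinophil markers were measured, and Ear1, Ear2 and Siglec5 (Siglecf) are also on the alveolar macrophage list. Under the filter, Ccr3 had 51 reads against 8, a ratio of 0.143 (0.0588 to 0.305). Cebpe had 16 against 2 (0.0128 to 0.486) and Il5ra 46 against 27 (0.321 to 0.882), while Epx and Prg3 had at most 1 read. Neutrophil markers went both ways, 2 higher (S100a8 and S100a9) and 1 lower (Retnlg, at 79.5 FPKM in wild type and 22.1 in the knockout), with a median of 0.41, and NK cell markers had a median of 0.12. Erythroid genes were higher in 5 of 8 members (median 1.11, above all random lists), with Hba-a1 at 7073 FPKM against 3153. Endothelial markers had a median of 0.46 with none past the size rule, and Clec14a, an endothelial lectin outside the list, was at 92.4 against 36.7. Heart muscle markers, which the heart-derived muscle sleeve of the pulmonary veins also expresses, were lower in all 8 measured members (median -1.42), with Nppa at 9.97 against 0.701 and Myl7 at 88.1 against 28.9. All 10 smooth muscle markers lay below 0 and 1 of them, Actg2, passed the size rule (median -0.44). Of 5 measured fat cell markers 4 lay below 0, and Cfd and Adipoq were past the size rule (median -0.57). The median for alveolar type II cells was -0.07, for club cells 0.12 and for reference genes -0.05.

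The higher genes were fewer. Dbp (chromosome 7, 45705088 to 45710203), an output gene of the circadian clock, was at 48.6 FPKM in the knockout and 15.7 in wild type, and the 13 measured clock genes had a median of 0.52, above all random lists. Its antiphase partners Nfil3 and Arntl had differences of -1.17 and -0.70, the only 2 of the 13 below 0, and the other 11 lay above 0. Inmt (chromosome 6, 55170626 to 55175043), a methyltransferase abundant in lung fibroblasts, was at 2511 against 1031, and Hpgd, which breaks down prostaglandins, had a difference of 1.21. Tcf21, a transcription factor of lung fibroblasts, was at 95.7 against 43.9. Rps27, a ribosomal protein gene, had the largest difference among the higher genes outside the small RNAs, at 211 against 17.3 FPKM, and the processed pseudogene Rpl34-ps1 was at 11.4 in wild type and under 1 read in the knockout. Both values are taken as uncertain, since near-identical copies elsewhere in the genome can share their reads, which was not tested. The 24 ribosomal protein genes had a median of 0.06.

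**Figure D1:**
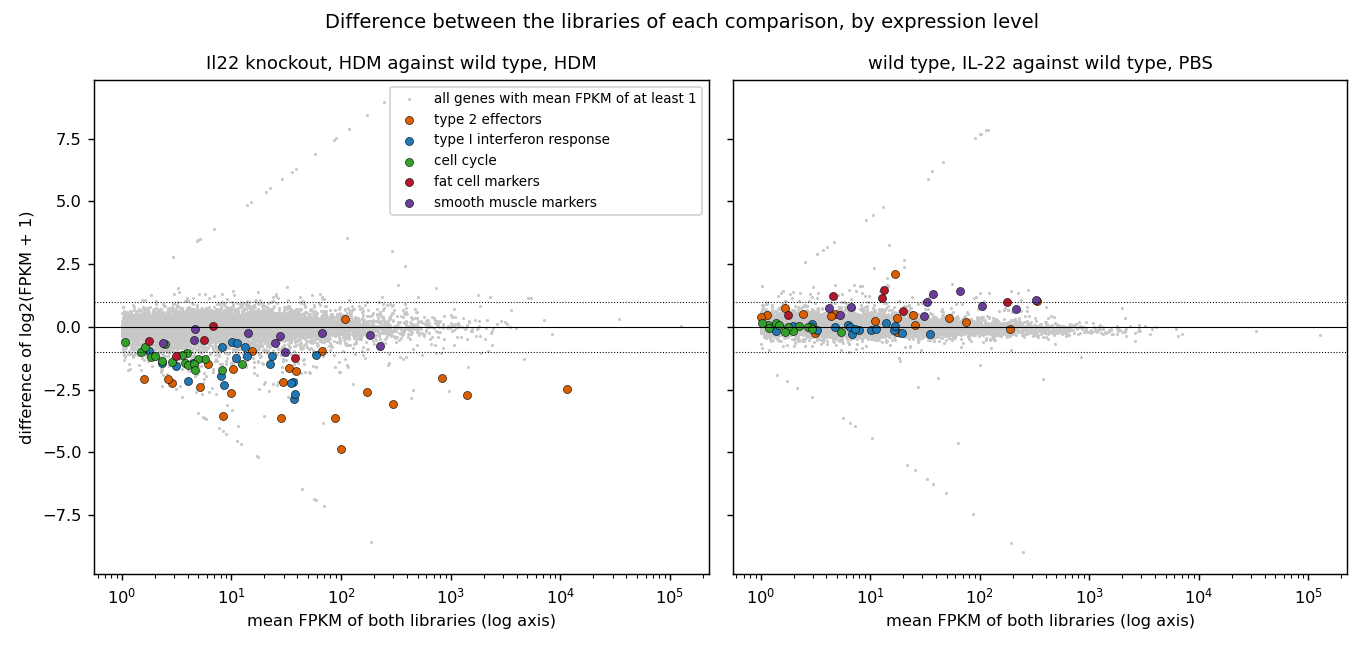
Difference of log2(FPKM + 1) between the libraries of each comparison (vertical axis) against the mean FPKM of both (log axis), one point per gene with a mean FPKM of at least 1, with genes of 5 fixed lists in colour and dotted lines at the size rule. The type 2 effector genes other than Postn lie below 0 in the knockout comparison (median -2.20) and mostly above 0 in the IL-22 comparison (median 0.42), and the grey points along slanted lines are mainly small RNAs listed at or near 0 in 1 library.

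**Figure D2:**
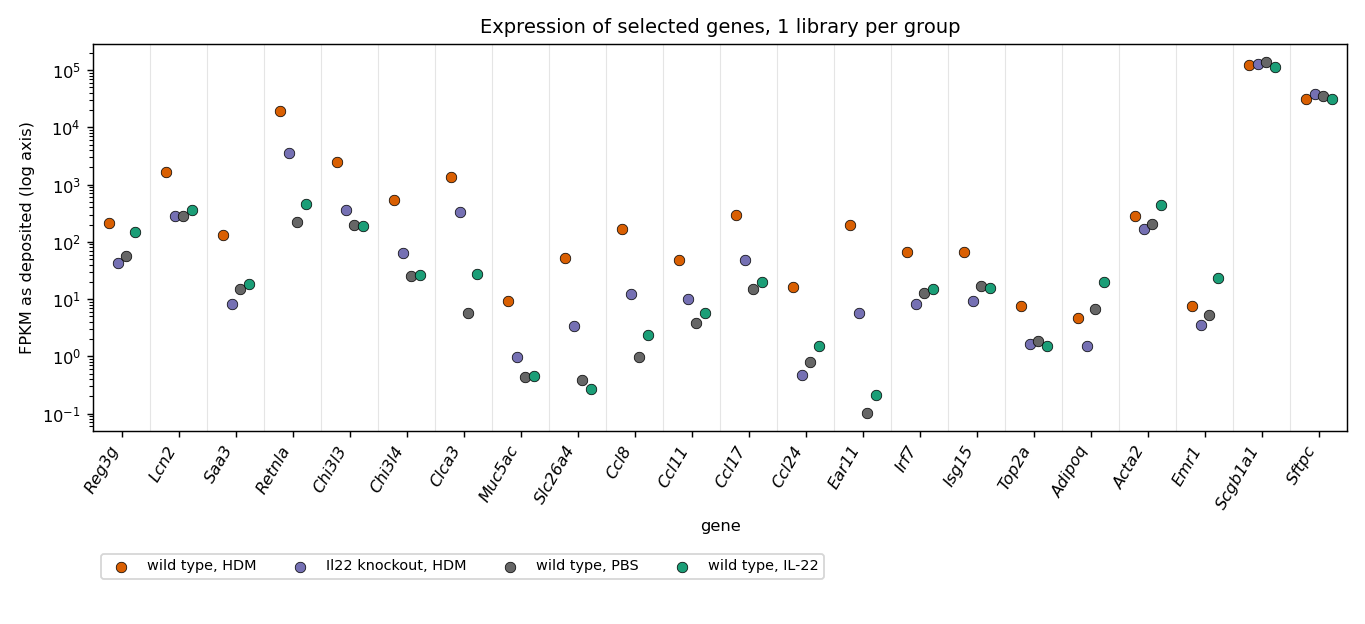
FPKM as deposited (log axis) of 22 genes in the 4 libraries, 1 point per library, with values of 0 not drawn. Retnla is at 19372 FPKM in the wild-type HDM library, 3511 in the knockout HDM library, 221 with PBS and 454 with IL-22, while the cell markers Scgb1a1 and Sftpc are alike in all 4.

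The HDM and the PBS and IL-22 libraries stand in separate tables that may have been normalized separately, so levels across them are given only side by side. For Retnla the levels were 19372 FPKM in the wild-type HDM library, 3511 in the knockout HDM library and 221 with PBS. For Clca3 they were 1343, 326 and 5.79, and for Ear11 195, 5.71 and 0.103. The knockout HDM library thus lay between the others for these genes. For Reg3g (214, 43.4 and 57.2), Saa3 (130, 8.15 and 15.3), Isg15 (66.4, 9.44 and 17.1) and Ccl24 (16.2, 0.471 and 0.781) it lay below the PBS library, and for Lcn2 (1663, 284 and 281) close to it. The type I interferon list had a mean log2(FPKM + 1) of 4.24 in the wild-type HDM library, 2.71 in the knockout HDM library and 2.79 with PBS.

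The other comparison asked what IL-22 placed in a lung without allergen does after 24 h. Few genes differed by the size rule: of 13233 measured genes 79 were higher with IL-22 and 25 lower, and 97.6% lay within 1.5-fold. Small RNAs, whose FPKM is unstable because the transcripts are short, made up 17 of the higher and 19 of the lower genes, which leaves 62 higher and 6 lower. Macrophage, goblet cell, fat cell and smooth muscle genes were among those higher with IL-22, and Reg3g was at 146 FPKM with IL-22 and 57.2 with PBS, a difference of 1.34.

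The largest difference outside the small RNAs and unnamed genes was that of Slc13a3 (chromosome 2, 165405028 to 165473230), a sodium-coupled dicarboxylate transporter, at 27.9 FPKM with IL-22 and 1.96 with PBS. Fcrls (chromosome 3, 87250758 to 87263738), an Fc receptor-like scavenger receptor of macrophages, was at 36.0 against 4.88, and Cd72 (chromosome 4, 43446462 to 43454628), a lectin of B cells and macrophages, at 35.0 against 5.89. Cxcl13 (chromosome 5, 95956951 to 95961068), the chemokine of B cells, was at 18.8 against 2.91. Emr1 (Adgre1, the F4/80 antigen of macrophages, chromosome 17, 57358691 to 57483527) was at 23.3 against 5.21, Aif1 at 22.4 against 6.39 and Siglece at 13.2 against 3.64. Of 17 monocyte and interstitial macrophage markers 3 were higher and none lower (median 0.33, above all random lists), among them C1qb at 129 against 56.0. The alveolar macrophage markers had a median of -0.20, below all random lists, with Itgax at 9.18 against 13.6 and the exception of Fabp4, which fat cells also express, at 175 against 67.1. No difference past the size rule was found in the eosinophil, neutrophil or T cell markers.

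Some goblet cell and other secreted genes of the airway were higher. All 9 measured goblet cell and mucus genes lay above 0 and 3 were past the size rule (median 0.42, above all random lists), with Clca3 at 27.9 against 5.79 FPKM and Bpifb1 at 324 against 152. Bpifa1 (chromosome 2, 154142880 to 154149219), a secreted defence protein of the upper airways, was at 321 against 124. Of the 13 club cell markers only Retnla passed the size rule and the median was 0.03, with Scgb3a1, a secretoglobin, at 2515 against 1500 but Scgb1a1 at 112693 against 141280 and Cbr2 at 5715 against 7280. Muc5ac was at 0.457 against 0.438. Type 2 effectors had a median of 0.42 over 17 measured genes, 2 of them higher, namely Clca3 and Retnla (454 against 221). Ccl8 and Ccl11 were at 2.36 against 0.975 and 5.80 against 3.79. Chemokines had a median of 0.34, with Cxcl13 the only called member.

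Of the 20 measured genes known to respond to IL-22 or STAT3 in epithelium, Reg3g alone passed the size rule, and the median was -0.01, whose sign depended on the scaling. Saa1, an acute phase gene, had a difference of 0.90. Ltf (lactoferrin) was at 39.4 against 19.8, Lcn2 at 357 against 281, Saa3 at 18.7 against 15.3 and Socs3, the feedback inhibitor of STAT3 signalling, at 12.4 against 9.30. Il22ra1 had 98 reads with IL-22 and 45 with PBS, a ratio of 1.51 after depth with an exact 95% interval of 1.05 to 2.196. Orm1 and Orm2, acute phase glycoproteins with near-identical copies, were at 7.87 against 1.77 and 2.67 against 0.437.

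Fat cell markers were higher in 4 of 6 measured genes (median 1.08, above all random lists), with Adipoq (adiponectin, chromosome 16, 23146536 to 23158028) higher by 1.46 and Cfd (adipsin) at 239 against 118. Car3, a carbonic anhydrase of fat and muscle, was at 86.7 against 26.0. All 10 smooth muscle markers lay above 0 and 3 were past the size rule (median 0.81), with Acta2 at 445 against 209 and Cnn1 at 97.6 against 35.9. All 10 heart muscle markers lay above 0 (median 0.37), with Nppa at 22.5 against 6.54, and the skeletal muscle gene Tnnt3 was at 11.4 against 2.84. The ciliated cell markers had a median of 0.27 and alveolar type I markers of -0.19, in each case with none past the size rule.

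Lower with IL-22 were Egr1, an immediate early gene, at 10.6 against 26.1 FPKM, and Zbtb16, a glucocorticoid-responsive gene, at 3.94 against 8.94. The 18 immediate early and stress genes had a median of -0.30, below all random lists. Fos was at 5.77 against 11.1, short of the size rule. The brain cytoplasmic RNA Bc1 and the pseudogene Oaz1-ps, both with copies in the genome, were lower by size as well (-1.93 and -1.37). Bc1 is a short RNA listed at 0 with IL-22 and at 2.80 FPKM with PBS, so its difference is taken as uncertain. Tgoln2 and Rpl26 (higher) and Btg3 (lower) were at under 1 read in 1 of the libraries and at 5.05, 2.07 and 3.51 FPKM in the other, and these values are taken as uncertain. Interferon genes of type I had a median of -0.10, which turned to 0.00366 with scaling to a common total, and cell cycle genes of -0.02, with none past the size rule.

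**Figure D3:**
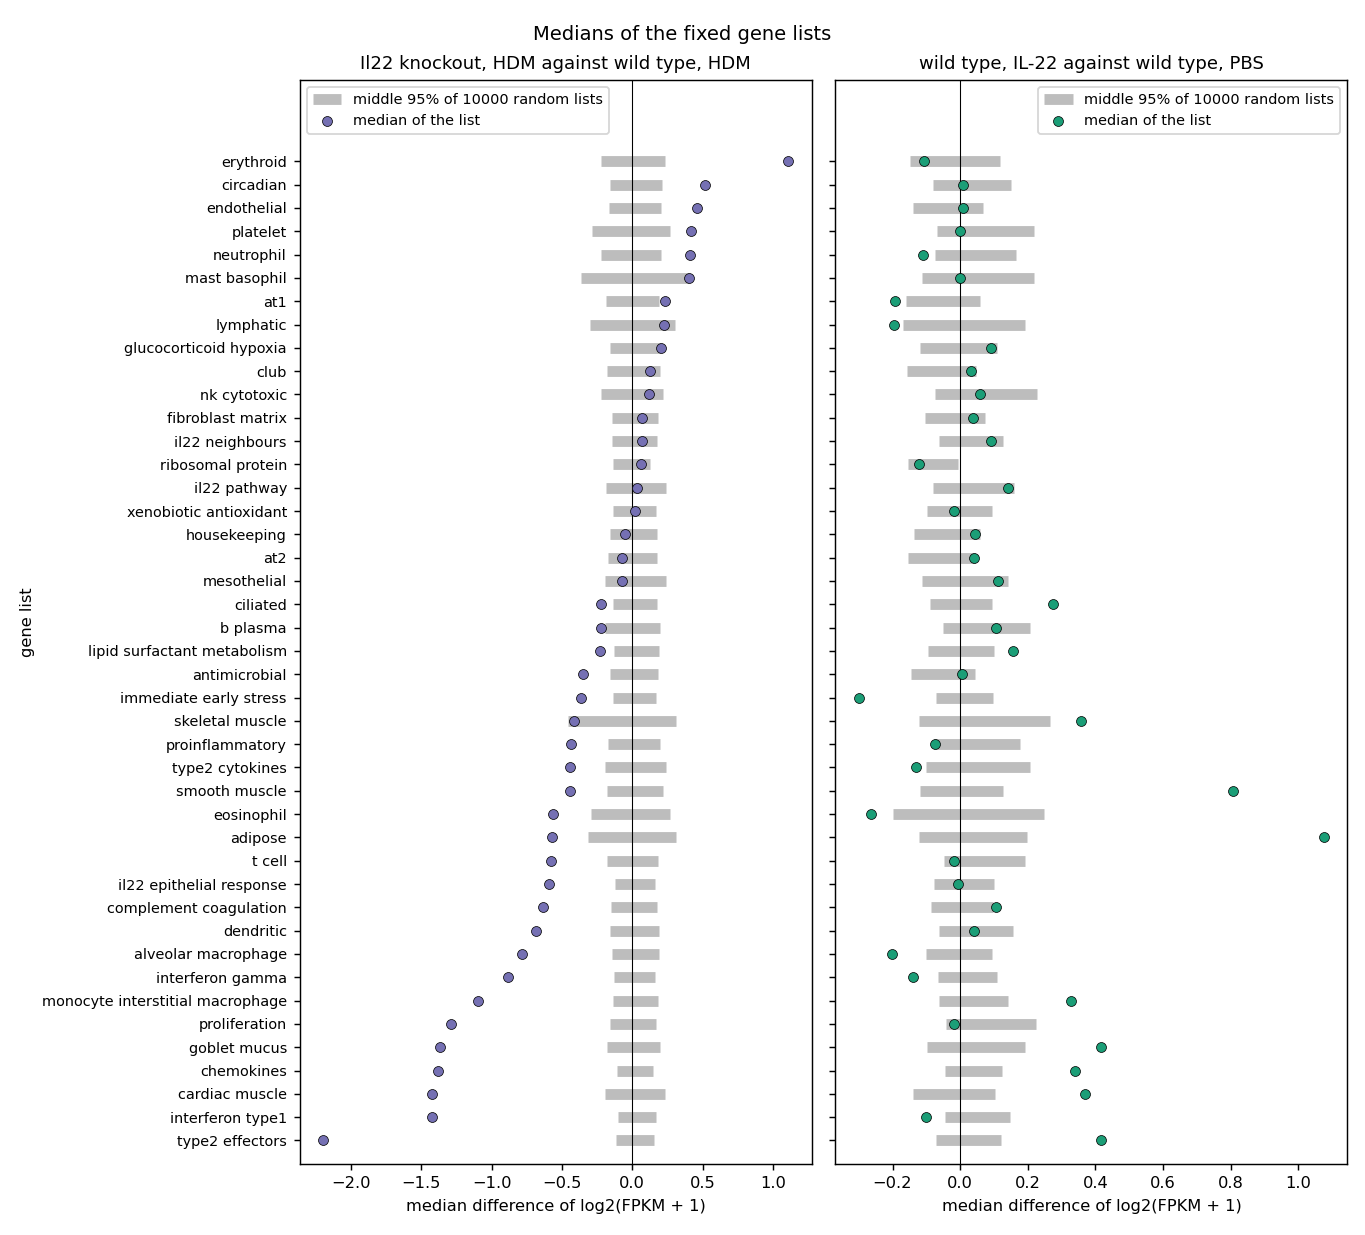
Median difference of log2(FPKM + 1) of each fixed gene list with at least 3 measured genes, in the knockout comparison and in the IL-22 comparison, with grey bars for the middle 95% of 10000 random lists of the same size matched on expression. The type 2 effectors (median -2.20) and the erythroid genes (median 1.11) are at the ends in the knockout comparison, and fat cell (1.08) and smooth muscle (0.81) markers lead in the IL-22 comparison.

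The comparisons were then set against each other, to ask whether genes that were higher when IL-22 was added were lower where it was absent. Of the 65 genes higher with IL-22 and measured in both comparisons, 29 were lower in the knockout HDM library and 1 higher, where 1.26 and 0.292 would be in common if the lists were independent. Their median difference was -0.92, below all random lists, and -0.89 for the 54 left without small RNAs, of which 53 lay below 0. These included Reg3g (1.34 with IL-22 and -2.28 in the knockout), Clca3 (2.09 and -2.04), Retnla (1.04 and -2.46), C1qb (1.19 and -1.80), Cxcl13 (2.34 and -1.65), Orm1 (1.68 and -1.72) and Adipoq (1.46 and -1.16). Slc13a3 (3.28 and -0.46) and Bpifa1 (1.36 and -0.35) lay below 0 in the knockout without passing the size rule. The 16 genes lower with IL-22 also lay low in the knockout, with a median of -0.51, below all random lists, 4 lower and 3 higher. Most were small RNAs, and the 5 others, with the short RNA Bc1 among them, had a median of -0.03. Across 12902 genes the differences of both comparisons had a Pearson correlation of -0.16 and a Spearman correlation of -0.10, where genes are not independent replicates.

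**Figure D4:**
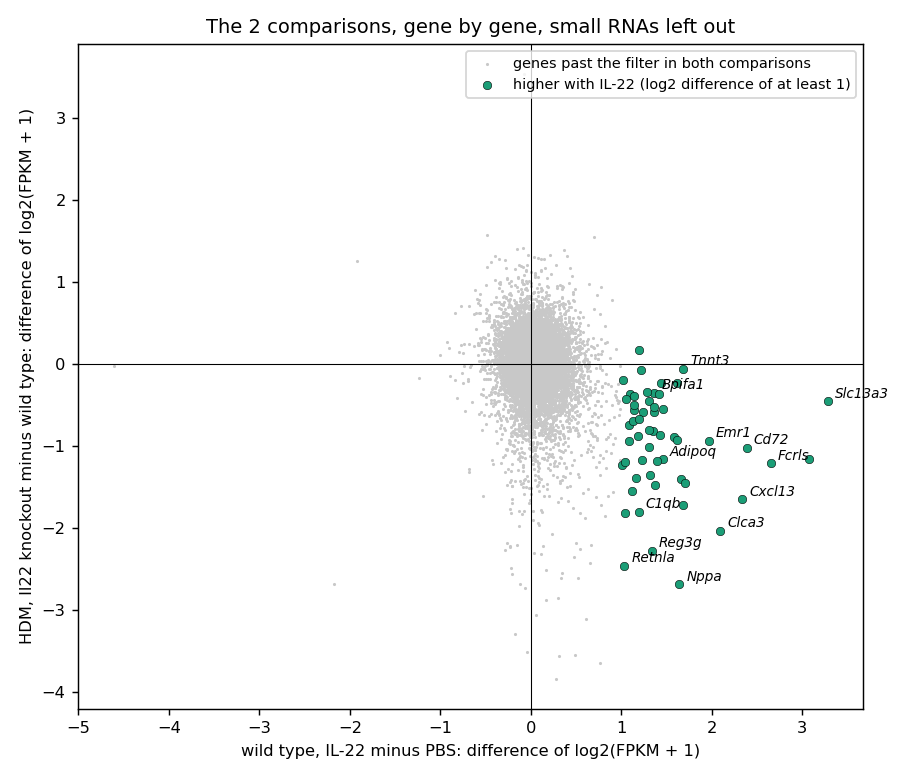
Difference of log2(FPKM + 1) between IL-22 and PBS (horizontal axis) against that between the knockout and wild type after HDM (vertical axis), one point per gene measured in both and without small RNAs, with genes higher with IL-22 in green. Of these 54 genes 53 lie below 0 on the vertical axis, with a median of -0.89.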

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

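Leaving out small RNAs and leaving out the fat, smooth muscle, heart and skeletal muscle lists were chosen after the result was seen, and the other settings before the data were examined. With 1 library per group the limit of every result is the missing replicate, and low genes rest on few reads. The medians of the genes higher and lower with IL-22 in the knockout comparison, and both correlations across genes, kept their sign. They moved by less than 1.5-fold under each setting run. For the genes lower with IL-22 this bound is wider than the median itself. Without small RNAs their median went from -0.51 to -0.03, inside the range of random lists, so that result rests on the small RNAs. Counts moved with the thresholds. With a pseudocount of 0.1 there were 131 higher and 488 lower genes in the knockout comparison (73 and 322 as reported) and 132 higher with IL-22 (79 as reported), since the difference of low genes is then larger. A size rule of 1.5 left 25 higher and 126 lower in the knockout and 31 higher with IL-22, and a mean FPKM of at least 5 left 193 lower in the knockout, since fewer genes pass. Without small RNAs 6 genes were lower with IL-22, not 25, and 91.2% of called genes were higher, against 76.0%. With the size rule of 1.5 this share was 59.6%. Scaling to a common total moved the median of all genes with IL-22 from 0.04 to 0.13, and that of the IL-22 response list from -0.01 to 0.09. Of the lists whose median lay outside the middle 95% of random lists, 6 changed sign under some setting, and so did the medians of other lists that were near 0. In the knockout comparison mast cell and basophil markers were at -0.11 with scaling to a common total and -0.0757 with no filter, and platelet markers at -0.35 with a mean FPKM of at least 5. With IL-22, type 2 cytokines were at 0.0172, eosinophil markers at 0.0292 and type I interferon genes at 0.00366 with scaling to a common total, and eosinophil and neutrophil markers at 0.0237 and 0.0151 with no filter. The cause was not tested. Of 579 and 585 values of named genes under other settings, 18 and 12 moved by over 1.5-fold, all with the pseudocount of 0.1, and no called gene changed sign. With 10 expression bins, 1 of 43 list percentiles in the knockout comparison and 10 of 43 with IL-22 moved by over 2.5 points, and none of these 11 crossed into or out of the middle 95%.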

Other observations

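Il10, the gene of an anti-inflammatory cytokine, lay just under the filter and was singled out after its values were seen. It had 59 reads in the IL-22 library and 1 in the PBS library, a ratio of 40.8 after depth with an exact 95% interval of 7.05 to 1640 for counting error, and 6 and 1 reads in the wild-type and knockout HDM libraries. Il22ra2, the soluble receptor that binds and blocks IL-22, was at 0.176 FPKM in the wild-type HDM library and 0.887 in the knockout HDM library. This is about 10 against 56 reads, a ratio near 5.12 (2.59 to 11.3), with about 46 reads with PBS and 40 with IL-22. The estimated reads of this gene lay off whole numbers, so these counts and the ratio are approximate. The granule genes Ngp and Camp of immature neutrophils were at 26.8 and 19.4 FPKM with PBS, 14.9 and 11.3 with IL-22 and at most 0.839 and 0.370 in the HDM libraries, across tables that may have been normalized separately. Il17a, Il17f, Il25 and Il31 were listed at 0 in all 4 libraries, and Il9 had 1 read in the IL-22 library and 0 elsewhere.

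Among receptors and matrix genes, the macrophage receptor Marco was at 3.07 and 4.43 FPKM in the wild-type and knockout HDM libraries and 25.3 and 21.6 with PBS and IL-22. Pigr, which carries IgA across epithelium, was at 173 FPKM in the wild-type HDM library and 55.9 in the knockout, and 39.0 and 43.2 with PBS and IL-22. The stearoyl-CoA desaturase Scd1 was at 512 FPKM with IL-22 against 297 with PBS, and the 15 sterol and fatty acid synthesis genes had a median of 0.16 with IL-22 and -0.23 in the knockout. Xenobiotic and antioxidant genes had medians of -0.02 and 0.02. The complement and acute phase list had a median of -0.64 in the knockout, with C3 at 239 against 546 FPKM.

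In the following, the tests of the type 2 pattern and of the genes higher with IL-22 were chosen after the result was seen. The tests of the fat, smooth muscle and macrophage pattern were chosen after that pattern was seen but before their own values were computed. The type 2 effector genes were lower in the library labelled knockout, although the series title names IL-22 as an inhibitor of allergic airway inflammation. A difference in scaling is argued against, since the median of all genes was 0.03 and 90.4% of them lay within 1.5-fold. Median ratio scaling therefore moved the values little, and the list's median was -2.22 after it. A lower share of leukocytes stays open: the 7 measured goblet cell genes outside the type 2 effectors had a median of -0.996, but such genes also answer to IL-13 from leukocytes, so this decides nothing. Swapped labels cannot be told apart from correct ones: the library labelled wild type had 13 reads of Il22 and Iltifb, which a null allele would not give, but the labels do not say which exons the allele lacks. Genotype, a weaker response to the allergen in the knockout library, and the time of collection, for which the clock genes differ, may each contribute. Handling and dissection may as well, and with 1 library per group all of these stay open. The immediate early and stress genes, fixed as signs of handling, had a median of -0.37 in the knockout comparison, with 13 of 17 measured genes below 0. Hspa1a was at 6.22 FPKM in the knockout against 33.8 in wild type.

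Adipose, smooth muscle and macrophage genes were higher in the IL-22 library. A large increase in macrophages of every kind is argued against. The 19 general macrophage genes chosen for this test had a median of 0.0489, with 11 above 0 and 8 below. That is under the 0.25 set in advance, but at percentile 96.4 of the random lists, near the top of their middle 95% (-0.118 to 0.0560). A small increase therefore stays open. More fat in the sample stays open: 15 further fat cell genes, measured for this test, had a median of 0.31 with 14 above 0. This lay above all random lists, but was short of the 0.5 set in advance and over the 0.25 below which it would have been dropped. More smooth muscle stays open in the same way, with a median of 0.25 over 19 further genes, against bounds of 0.4 and 0.2. Of these genes 14 lay above 0, and the median was again above all random lists. Both further lists thus moved in the direction that more fat and more smooth muscle would give, by less than the size set in advance. More macrophages of a particular kind stays open as well and was not tested.

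Genes higher with IL-22 were lower in the knockout library. Fat and muscle carried along in both comparisons is argued against as the whole cause. The median stayed at -0.89 for the 46 genes left without these lists and small RNAs, with 45 below 0. These 46 still hold Car3 and Fabp4, which fat also expresses. In the knockout comparison the further fat cell genes, 13 measured, had a median of -0.02, inside the range of random lists. Of these 8 lay below 0 and 5 above, which shows no clear difference in fat in that pair. The fixed fat cell markers had a median of -0.57 there, so a part from fat stays open. Macrophage content stays open: leaving out the macrophage lists gave -0.84 for the 50 genes left, but these still hold genes of myeloid cells such as Aif1 and Siglece, so this decides nothing. The 19 general macrophage genes had a median of -0.58 in the knockout comparison, below all random lists, with 18 below 0. With IL-22 their median was 0.0489. Whether the genes follow IL-22 itself or the strength of allergic inflammation, which also differed between the HDM libraries, stays open and was not tested.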
